A study of Saccharum officinarum with 24 samples.

How the data were processed

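Per the series' design text and the labels, RNA of the leaf +1 of sugarcane was hybridised on a custom two-colour Agilent array, 2 arrays for each of 12 time points, with a pool of equal parts of all the samples as common reference. The extraction was a modified Trizol method, per the labels. The labelling chemistry is given in 2 ways: the series' design text names an Agilent kit for low amounts of RNA, and the sample labels name a CyScribe kit. Scans were made on an Axon GenePix instrument and read with Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited scanner files give intensity values per spot and channel, not normalized, with local background, flags and Agilent's processed signals. They also give, as deposited, Feature Extraction's log10 ratio of red over green per spot. The authors also deposited a table of log2 ratios, whose scale and direction are not stated. This table was set against the log10 ratio of red over green computed from Agilent's processed signals of the same array. Duplicate spots were averaged, and probes with no difference between the channels were left out. The columns of the table gave correlations between -0.996 and -0.978 and slopes between -3.60 and -3.32 on 22 arrays. The 2 arrays of hours 20 and 22 after the first sampling in replicate set 1 are called the displaced arrays. Their spots matched the other arrays only when read 2 rows away. At hours 20 and 22 in turn, their correlations were -0.964 and -0.972 and their slopes -4.42 and -4.26. The authors' ratios are therefore taken as log2 of Cy3 over Cy5, with no turning for the dye swap. In the authors' deposited ratios a single repeated value filled 50.7% and 41.99% of the columns of the displaced arrays, against at most 0.064% of any other column. The column medians lay between -0.22 and 0.02, and how they were centred stays unknown.

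The scanner intensities were background-corrected with normexp (offset 50) and normalized within arrays by loess in limma 3.58.1 under R 4.3.3. Control spots (1417 of 45220) had weight 0, and spots flagged as outliers were left out. Duplicate spots of a probe were averaged. Each log2 ratio was turned to sample over pool from the dyes in the labels. Probes were tested where the sample channel was well above background on both arrays of at least 1 time point. The lowest and highest median green signals of the arrays were 104 and 183 over backgrounds of 45.5 to 60.0, and the red medians were 37.6 to 51.9 over 35.0 to 37.0. Between 0 and 46 green spots per array were saturated and were kept.

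Differences among the 12 time points were tested with a moderated F-test in limma (12 residual degrees of freedom per probe); 1 probe had no value at some time point and was not in this test. Rhythms were tested with a cosine and a sine of 24 h period, and the dawn comparison was a contrast in the fit of 12 groups. p-values were adjusted by the Benjamini-Hochberg method over the tested probes, at a threshold of 0.05. Each probe's amplitude, SE and peak time came from the cosine fit. Probes were named by a rule set before the data were examined: among probes past both tests whose replicate sets peaked within 3 h of the joint fit, the 2 largest amplitudes with peaks in the 12 h after dawn and the 2 largest in the other 12 h; for the dawn comparison, up to 2 rises and 2 falls past the threshold. Gene lists set before the data were examined, with their tests, were not run because the files do not pair probes with genes.

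The tests were checked on simulated data with the spread of the 8715 tested probes and 200 changed probes. The simulated noise was independent between arrays, with no effect shared by a replicate set or slide. Far fewer probes changed than were called in the rhythm and day tests of the real data. The shares below therefore describe the simulated setting and not the power of the tests on the real arrays. The rhythm test called 62.0% of simulated rhythms of amplitude 0.25, 89.5% of amplitude 0.5 and 99.5% of amplitude 1. Unchanged probes made up 8.15%, 5.29% and 2.45% of the calls in these single draws, and over 40 draws on average 5.04% at amplitude 0.25 and 4.97% at 0.5, within 1.06% to 8.96%. The F-test over the day called 0%, 76.5% and 99.5% of these. In the dawn comparison, 81.0% of changes of 1 and 97.0% of changes of 2 on the log2 scale were called.

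The replicate number marks a shared dye orientation and set of slides, per the labels and the file headers, so the numbers pair the arrays. The fits reported leave this pairing out, as set before the data were examined, and the fit with replicate set as a block is an alternative. The deviations from the time means, replicate set 1 minus its mean with set 2, at 2 time points correlated across probes at 0.24 to 0.73 in all 45 pairs of the 10 time points without the displaced arrays; over all 12 time points the lowest value was -0.11. Dye orientation and replicate set cannot be separated. The 6 slides held 4 arrays each, 4 consecutive time points of 1 replicate set, and the last 4 time points of both sets were scanned on the later of 2 scan days. The consensus correlation within a slide was 0.29.

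Alternatives set before the data were examined were Agilent's processed signals, no background correction, median centring, Aquantile after loess, the authors' log2 ratios, other filters on dim probes, blocks for replicate set, slide and scan day, a threshold of 0.01, a 12 h harmonic, and leaving out each array or replicate set. Chosen after seeing the data were the settings without the displaced arrays, with these realigned by 2 rows, without the 4 arrays of the last 2 time points, with replicate set 1 alone without its displaced arrays, with combined settings, with a filter on the 22 other arrays, and with only the 4 arrays around dawn, as was the comparison of SS and AS probes at matched intensity (10000 draws of SS probes from 20 intensity bins).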

Results

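Leaf transcript levels of sugarcane variety SP80-3280 were followed over 1 winter day on 24 two-colour arrays. The leaf +1 of 4-month-old plants was taken every 2 h at 12 time points, starting 1.5 h before dawn. Times are given below as hours after the first sampling, so the samples are hours 0 to 22 and dawn was at hour 1.5. Each sample was a mix of 3 individuals. Every time point had 2 arrays, one per replicate set, and each array set the sample against an equimolar pool of all samples. In replicate set 1 the sample carried Cy3 and in replicate set 2 it carried Cy5, and the labels call the second array a dye swap of a biological replicate. Values are given as log2 of sample over pool, so 0 is the level of the pool. With 2 arrays per time point, the number of arrays limits the precision of every value.

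The array held 21902 probes of 60 bases. Their names carry SS for 14522 probes and AS for 7380, and 7378 of the 7380 AS probes were exact reverse complements of an SS probe of the same number. The names of the probes give no gene, so probes are reported by their IDs. On 22 arrays, between 38.4% and 54.4% of green spots and between 33.0% and 42.3% of red spots were well above background. A probe was tested if its sample channel was well above background on both arrays of at least 1 time point. This held for 8715 probes (39.8%), of which 8480 were SS probes (58.4% of all SS probes) and 235 were AS probes (3.18% of all AS probes).

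At 10 of the 12 time points the log2 ratios of both replicate sets correlated across tested probes with r between 0.60 and 0.73 (probes are not independent replicates). At hours 20 and 22 the correlations were -0.02 and -0.04. The arrays of replicate set 1 at these times stood apart from all others. Their raw green signals correlated with the median of the other arrays at -0.003 and 0.002 spot for spot, and at 0.49 and 0.44 when the spots were read 2 rows up or down. On the other 22 arrays the correlation was 0.95 or higher with no displacement and at most 0.015 at any other. These 2 arrays are called the displaced arrays. They stayed in the tests as designed, and the leading counts are also given without them. Arrays of a replicate set taken at different times of day reached correlations as low as -0.42 in set 1 and -0.56 in set 2. The dyes stated in the labels set the direction of every ratio.

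**Figure D1:**
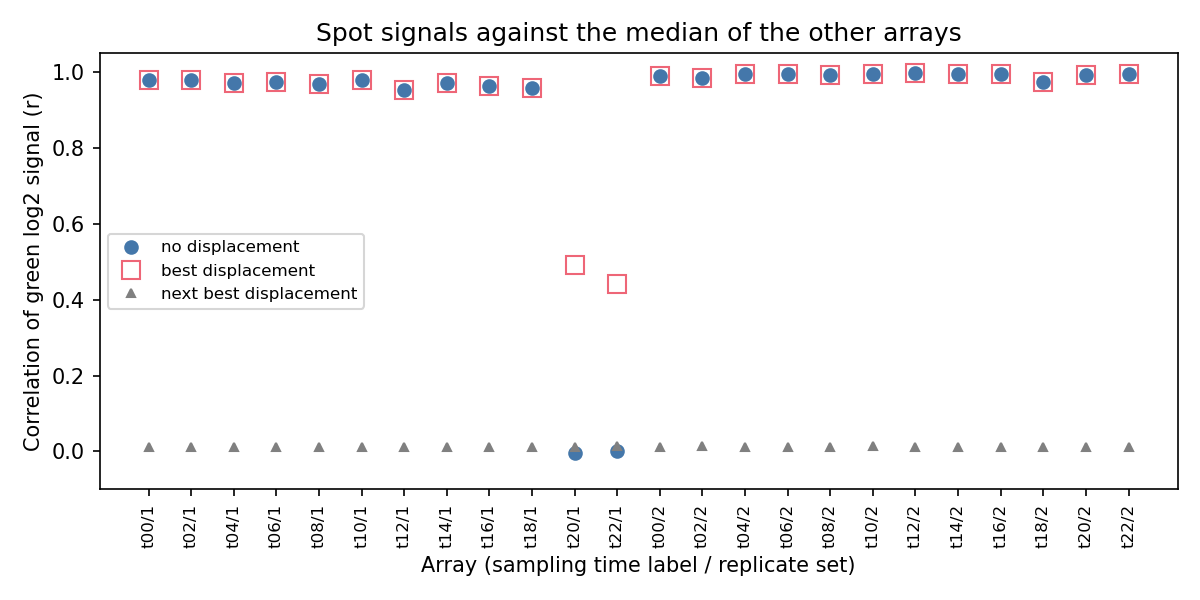
Each point is the Pearson correlation (r) of the green log2 spot signals of an array with the median of the other arrays, with no displacement, at the best of 231 row and column displacements, and at the next best. The horizontal axis names arrays by hours after the first sampling and replicate set; 22 arrays lie at 0.95 or higher with no displacement, and the arrays t20 and t22 of set 1 lie near 0 there and at 0.49 and 0.44 at a displacement of 2 rows.

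The first comparison asked which transcripts changed over the day. The log2 ratios of 3465 of the 8715 tested probes (39.8%) differed among the 12 time points in limma's moderated F-test at an adjusted p of 0.05, and the time means of these probes spanned a median of 1.081 on the log2 scale. The count was 3478 without the displaced arrays and 3617 without all 4 arrays of hours 20 and 22. With the replicate set as a block and without the displaced arrays it was 5283. It was 0 with median centring in place of loess. Under median centring an intensity-dependent dye bias of opposite sign stayed in the replicate sets. The median correlation of log2 ratio with intensity was 0.61 in set 1 and -0.60 in set 2, against -0.02 and 0.04 after loess. With the replicate set as a block, median centring still gave far fewer probes than loess, and the cause of that gap was not tested.

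The second comparison asked which transcripts followed a 24 h rhythm and when they peaked. A 24 h cosine passed limma's moderated F-test for 5710 of 8715 probes (65.5%), among them 3389 of the 3465 probes that differed over the day. Most rhythms were shallow. The median amplitude, which is the log2 distance from the mean to the peak, was 0.28, a peak 1.48-fold above the trough. An amplitude above 0.5 was found for 1196 rhythmic probes and one above 1 for 253. Fitted to each replicate set alone, the peaks lay within 3 h of each other for 80.5% of all tested probes, where unrelated times give 25%. With probes chosen on replicate set 2 alone (4458 rhythmic), the peak in set 1 lay within 3 h for 95.1%, against 65.3% of the probes that did not pass in set 2. Without the displaced arrays 5827 probes were rhythmic, and 5583 of these were among the 5710. The count was 3591 for replicate set 1 alone (4179 with its displaced arrays left out), 3437 with the slide as a fixed block and 25 with median centring. Each slide held 4 consecutive time points, so 30.02% of the variation of a 24 h cosine lay within slides and was left to a fit with the slide block. The replicate sets lay on separate slides with opposite dyes. The 95.1% of peaks within 3 h between sets argues against effects particular to single slides as the source of those rhythms. An effect shared by the slides of the same hours in both sets was not excluded. Sampling covered about 1 cycle, so the period was fixed and a repeat on a further day was not measured.

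Fitted peak times fell into 2 groups, one near dawn and one about 12 h later. Of the 5710 rhythmic probes, 710 (12.4%) peaked in the 2 h bin centred on hour 2 and 732 (12.8%) in the bin centred on hour 14. The fewest, 294 (5.15%), peaked in the bin at hour 20. Loess centres each array's log ratios near 0, so a rise of many probes at one time is set off by falls at others, and peak counts are relative to the other probes. Large amplitudes were most frequent near dawn: 244 of the 710 probes in the bin at hour 2 had an amplitude above 0.5, against 156 of 732 at hour 14 and 23 of 294 at hour 20. Without the displaced arrays the bins at hours 2, 14 and 20 held 10.6%, 11.2% and 6.11%. With the slide as a fixed block they held 5.44%, 3.84% and 9.92% of 3437 probes, and the 2 maxima were not seen.

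**Figure D2:**
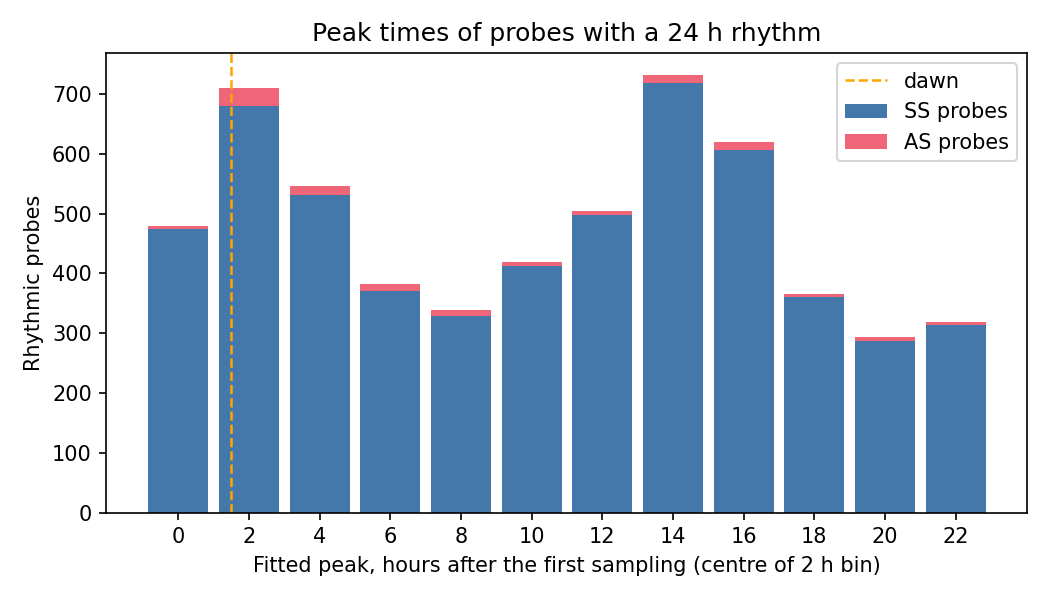
Number of rhythmic probes (vertical axis) by fitted peak time in hours after the first sampling (horizontal axis, 2 h bins centred on the sampling times, dashed line at dawn), with SS and AS probes stacked. The bins at hour 2 (710 probes) and hour 14 (732 probes) are the fullest and the bin at hour 20 (294 probes) is the emptiest.

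Named by size among the probes that passed both tests, 2 probes had fitted peaks in the 12 h after dawn and 2 in the other 12 h. Probe GS1_SS_18856_00961, with the sequence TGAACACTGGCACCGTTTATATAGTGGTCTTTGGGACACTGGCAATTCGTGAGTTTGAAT, had an amplitude of 2.70 ± 0.31 (SE, 24 arrays) and peaked at hour 2.45, 0.95 h after dawn (adjusted p = 6.6e-07, limma). It was saturated on 1 array, that of hour 4 in replicate set 1. Its mean log2 ratio was 1.84 at hour 4 and -4.33 ± 0.64 (SD, n = 2) at hour 16. Probe GS1_SS_16841_18244, with the sequence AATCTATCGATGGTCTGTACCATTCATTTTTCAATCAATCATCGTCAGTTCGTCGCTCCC, peaked at hour 8.23 with an amplitude of 2.5 ± 0.44 (SE; adjusted p = 0.00013, limma). Without the displaced arrays the amplitude was 3.24 (adjusted p = 1.1e-07, limma), and with scan day or slide as a fixed block it was 4.16 or 4.09. In replicate set 1 alone it was 1.60 and did not pass (adjusted p = 0.17, limma) with the displaced arrays, and was 3.34 (adjusted p = 9.4e-05, limma) without them, against 3.40 in set 2. The probe was saturated on the arrays of hours 6, 8 and 10 of replicate set 1, where its highest log2 ratio was 0.98, against 2.68 in set 2.

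Probe GS1_SS_10186_07079, with the sequence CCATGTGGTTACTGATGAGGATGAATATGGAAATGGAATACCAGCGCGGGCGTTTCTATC, had an amplitude of 2.69 ± 0.18 (SE, 24 arrays) and peaked at hour 1.057, just before dawn (adjusted p = 1.3e-09, limma). Its replicate sets gave amplitudes of 2.64 and 2.75. Its lowest mean log2 ratio, -4.23 ± 0.34 (SD, n = 2), was at hour 14. Probe GS1_SS_13401_09072, with the sequence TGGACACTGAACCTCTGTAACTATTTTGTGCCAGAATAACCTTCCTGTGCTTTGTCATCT, had an amplitude of 2.47 ± 0.27 (SE) and a fitted peak at hour 19.3 (adjusted p = 3.8e-07, limma). The amplitude was 3.80 with either scan day or slide as a fixed block. Its mean log2 ratio was -4.51 ± 0.45 (SD, n = 2) at hour 6 and 0.60 ± 0.01 at hour 18. The fitted peak times of these 4 probes differed between replicate sets by at most 0.33 h. A peak of each set within 3 h of the joint fit was a condition for naming, so some agreement was selected for.

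**Figure D3:**
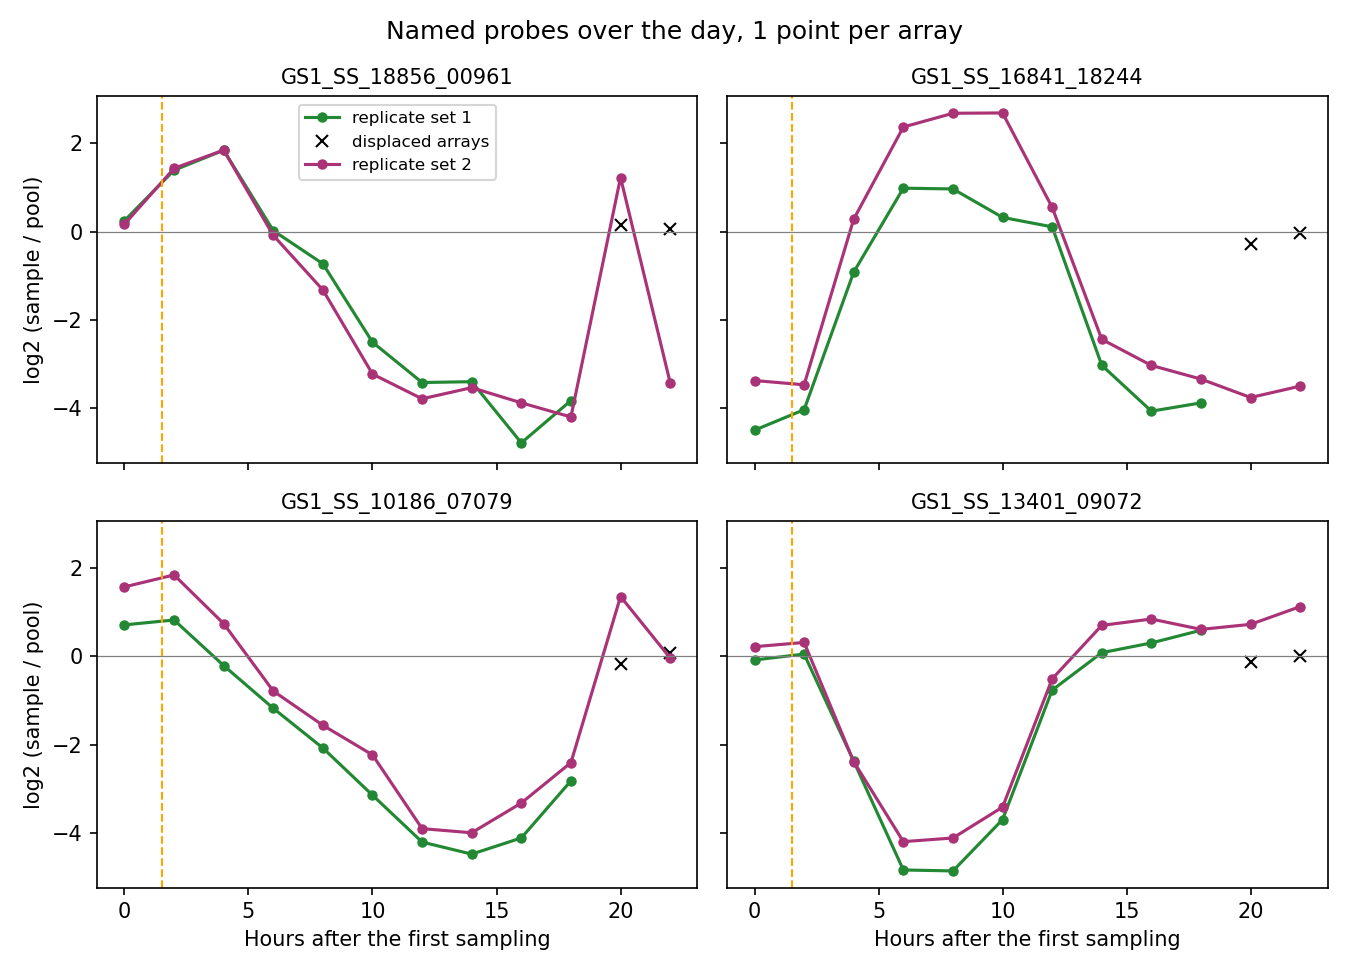
Log2 ratio of sample to pool (vertical axis) over hours after the first sampling (horizontal axis, dashed line at dawn) for the 4 named probes, 1 point per array, joined within a replicate set; crosses are the displaced arrays. For GS1_SS_16841_18244 set 1 lies below set 2 at every time point without a displaced array. The gap is widest at hour 10, with 0.32 in set 1 and 2.68 in set 2. This probe spans 5.47 in set 1 without the displaced arrays, with saturated spots at hours 6 to 10, and 6.43 in set 2.

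The third comparison asked what changed across dawn, from the first sample to the second, taken 0.5 h after dawn. In limma's moderated test 0 probes passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 142 probes, 76 higher and 66 lower after dawn, where chance alone gives about 436. Without the displaced arrays 0 probes passed the adjusted threshold and 238 the unadjusted one, and with the replicate set as a block as well the unadjusted count was 504. The median 95% half-width of a probe's change in the fit of 24 arrays was 0.38 on the log2 scale. The 142 probes, far fewer than chance gives, are a sign that this fit overstates the error of the dawn change. It leaves out the pairing and keeps the displaced arrays, so its 0 probes are weak evidence that nothing changed. In simulated data with the spread of these probes and independent noise, 81.0% of changes of 1 on the log2 scale were called in this comparison. In that blocked fit 1 probe passed the adjusted threshold. This was GS1_SS_25201_14196, named after its values were seen, which was higher after dawn by 1.23 ± 0.13 (SE; adjusted p = 0.00071, limma) and by 1.21 and 1.26 in the replicate sets. When the first array of replicate set 1 was left out, 1 other probe passed, GS1_SS_24414_20650, also named after its values were seen, at -1.41 ± 0.21 (SE; adjusted p = 0.042, limma). This leaves 1 array before dawn, which is assumed to vary like the other time points. With all arrays its changes were -0.19 and -1.36 in the replicate sets.

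The fourth comparison set SS against AS probes. A rhythm was found for 5580 of 8480 SS probes (65.8%, exact binomial 95% interval 64.8% to 66.8%) and for 130 of 235 AS probes (55.3%, 48.7% to 61.8%; two-sided Fisher's exact test, p = 0.0011). SS probes drawn to match the intensity of the tested AS probes were rhythmic in 57.9% (95% of draws between 51.5% and 64.3%), a range that includes the AS share. Without the displaced arrays the shares were 67.3% of SS and 52.3% of AS probes (two-sided Fisher's exact test, p = 3.1e-06), and the matched SS probes were rhythmic in 59.6% (53.2% to 65.5%), a range just above the AS share. Among probes well above background on all of the 22 other arrays the difference turned to -3.91 percentage points over 59 AS probes (two-sided Fisher's exact test, p = 0.57). The probes tested were not a random part of the array. Intervals and tests here and for the strand pairs below count probes or pairs, all measured on the same arrays, as independent. The spread between arrays or plants is not measured by them.

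Opposite-strand pairs peaked together more often than shuffled pairs. In 104 pairs both probes were tested, and in 48 both were rhythmic, where independence gives 40.5 (two-sided Fisher's exact test, p = 0.0012). In 39 of the 48 pairs (81.3%) the peaks lay within 3 h, against a median of 35.4% when partners were shuffled (permutation p = 1e-04, one-sided, the smallest that 10000 shuffles can give). The median difference of peak times was 0.92 h, and 2 pairs peaked 9 to 12 h apart. Without the displaced arrays 87.0% of 46 such pairs peaked within 3 h. With the stricter detection rule 6 such pairs were left, of which 66.7% peaked within 3 h (permutation p = 0.14).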

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

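The tests of the 2 array patterns below were chosen after the result was seen. The displaced arrays of replicate set 1, labelled hours 20 and 22, held signal that the comparisons did not use: read 2 rows away, their raw green signals correlated with the other arrays at 0.492 and 0.442. A hybridization that failed completely would give no such correlation at any displacement, and the values argue against it. They cannot exclude a weak or partial hybridization, which would leave some correlation. A spot grid displaced by 2 rows, in opposite directions on the 2 arrays, needs 1 displacement far above the rest, and the weaker array had 0.442 against at most 0.014 at its other displacements. A candidate explanation is therefore that the scanner software set the grid 2 rows off, so that their deposited values belong to other probes. It leaves part of the difference unexplained. Even read 2 rows away, the correlations stayed under the 0.95 or more of the other arrays. Only 7.45% and 4.80% of the green spots of the displaced arrays were well above background, against 38.4% or more on the other 22. No biological explanation was tested for this pattern.

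In replicate set 2 the array labelled hour 20 did not resemble its neighbour at hour 18 (r = 0.08 across the 872 brightest tested probes), whereas the array labelled hour 22 did (r = 0.84). An abrupt change of leaf RNA late in the night would appear in both replicate sets. After realignment, however, the same-label correlations between sets summed to 0.49 less than the cross-label ones (-0.489, bootstrap 95% interval over probes -0.653 to -0.348). The intervals in this paragraph cover the sampling of probes only. Each correlation compares single arrays, so the spread between arrays or plants is not measured. Exchanged labels in replicate set 1 are argued against, since exchanging them changed the summed neighbour correlations by -0.451 (-0.592 to -0.335). Exchanging the labels in replicate set 2 raised that sum by 0.935 (0.738 to 1.15), so an exchange of those 2 arrays is a candidate explanation, open because it treats the first sample as following the last and was found on the same data. No fit used exchanged labels.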

How the results depend on the processing

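The settings without the displaced arrays, without the last 2 time points, with combined choices and with the filter on 22 arrays were chosen after seeing the data. With 1 array left out at a time, the count over the day was 3153 to 3558, the rhythm count 5500 to 5772 and the dawn count 0 to 1 (1 without the first array of replicate set 1). The replicate block gave 4877 probes over the day, 6287 rhythmic probes and 0 at dawn, and ended no call; combined with leaving out the displaced arrays or the 4 last arrays it gave 5283 and 5373 probes over the day and 1 at dawn in both, with 504 at an unadjusted p under 0.05 in both. Median centring gave 0 probes over the day and 25 rhythmic ones, and 440 and 1459 with a replicate block; the dye bias that it left is measured above. It also ended the call of GS1_SS_13401_09072 (amplitude 2.26 against 2.47, adjusted p = 0.071, limma), which passed again with the replicate block (0.00010). Each replicate set alone gave 3591 to 4458 rhythmic probes, and 10.52% to 15.4% of peaks in the bin at hour 2, 10.004% to 16.7% at hour 14 and 3.40% to 6.15% at hour 20; set 1 alone gave 4179 rhythmic probes with its displaced arrays left out. The slide as a fixed block gave 3437 rhythmic probes with 5.44%, 3.84% and 9.92% in these bins, with 30.02% of the variation of a 24 h cosine left within slides; the amplitudes of 3 named probes rose under it and that of GS1_SS_18856_00961 was 2.68 against 2.70, and whether slide effects moved the peaks was not tested. The bins at hours 2 and 20 held 11.4% and 5.97% with Agilent's processed signals and 11.4% and 6.35% with the authors' ratios. The 3 bins held 10.6%, 11.2% and 6.11% without the displaced arrays and 10.6%, 11.2% and 6.37% without the 4 last arrays. For these 4 settings the cause was not tested. With probes well above background on all 22 other arrays, fewer were tested: 3649 of 5287 were rhythmic, the SS minus AS difference turned to -3.91 percentage points, and 66.7% of 6 pairs peaked within 3 h. The planned filter on all 24 arrays left 0 probes, so it gave no value. Aquantile changes no log ratio (largest difference 0), so its equal counts add no evidence. The dawn count was 0 under all other settings run, with 10 to 442 probes at an unadjusted p under 0.05 apart from 0 with median centring. Signal over background, lowest in the red channel, limited which probes could be tested.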

Other observations

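The counts per 2 h step were chosen after the result was seen. In the fit of 24 arrays, 334 probes passed an adjusted p of 0.05 in limma from hour 2 to hour 4, 221 of them higher and 113 lower. From hour 4 to hour 6 there were 837, with 372 higher and 465 lower. No other step up to hour 18 had more than 29, and the steps from hour 14 to 16 and from hour 16 to 18 had 0, with 200 and 127 probes at an unadjusted p under 0.05. The picture was less sharp with the replicate set as a block and without the displaced arrays. There the 2 morning steps had 1045 and 2068 probes, the 4 steps from hour 6 to hour 14 had 276, 384, 403 and 240, and these 2 evening steps 23 and 4. The 4 samples from hour 0 to hour 6 lay on 1 slide per replicate set. The step from hour 18 to hour 20 had 304, or 1483 in the blocked fit, but it rests on the arrays doubted above.

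Orders of the 12 time points were shuffled with replicate pairs kept together. Of 100 orders, the real one included, 1 gave as many as 5710 rhythmic probes, and the highest of the others gave 2564. A random order therefore rarely gives this count. Shuffling also breaks up the 4 consecutive time points of each slide, so it cannot tell a rhythm from drift between slides. With the slide as a fixed block the rhythm count was 3437. Of 100 pairings of the arrays of the 2 replicate sets, 1 gave as many as 3465 probes over the day, and the highest of the others gave 790. A random pairing therefore rarely gives this count. A 12 h component beside the 24 h rhythm passed for 1187 probes (13.6%). Shuffling the time order gave as many in 14 of 100 orders (highest 2734), but this moves the 24 h rhythm into the 12 h term and is no fair comparison. With the 24 h fit kept in place and only its residuals reordered, a test chosen after that result, 1 of 100 orders gave as many and the highest of the others gave 271. A random order of the residuals therefore rarely gives this count, but the arrays of hours 20 and 22 doubted above were part of this fit.

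Pairs of SS and AS probes that peak together may reflect antisense signal copied from the sense strand during labelling, or RNA of both strands with shared timing. Copying needs a detected sense strand. That SS probes read the sense strand is taken from their names alone, since no gene orientation was available. Of the 235 tested AS probes, 36.2% (exact binomial 95% interval 30.02% to 42.7%) had an SS partner well above background on no array. This argues against copying from the SS strand for those AS probes. Their SS partners were not tested, so they lie outside the pairs that peaked together. For the 48 pairs with both probes rhythmic, copying would favour the brightest SS probes; theirs lay at a median intensity percentile of 70.3 (bootstrap 95% interval 54 to 83.1), too wide to decide, so copying and shared timing cannot be told apart for these pairs.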
